A study of Mus musculus with 77 samples.

How the data were processed

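The labels list 77 mouse samples, 53 of ChIP-seq and 24 of RNA-seq, from sorted bone marrow cells of wild type and Cebpa KO mice. The values used here come from a deposited table of 44002 enhancers, each with a position in build mm9, an assigned gene, a class of stages, a class of bound factors and columns of values. Its 15 columns used here hold 1 deposited signal value per enhancer for each group of assay, stage and genotype, and each matches a group of 2 listed libraries, 30 in all, by the assay, stage and genotype in the column name. How the authors pooled or scaled the libraries into this signal is not given in the sources used here, nor is a log or count convention; the values are never negative, are not whole numbers and differ in sum between columns, so they were read as linear signal. The authors' 0 or 1 flags for each stage are an annotation of the enhancers, deposited with no stated criterion, and entered no comparison. The submitters' processing notes name Bowtie2, MACS2 and bedtools for ChIP-seq and STAR, featureCounts and DESeq2 for RNA-seq, with no versions. Depth per library is unknown, so no counting interval was computed.

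The 17 other value columns were not used: 6 of expression, 6 of a quantity that the labels do not describe, and 5 with no listed sample. Colony-forming granulocyte and monocyte progenitors, monocytes and all RNA libraries were therefore not analysed here. Gene names were taken from the table as given. Of the 10096, 9335 matched a symbol of the reference table and 727 more a synonym, which was used for names only. No annotation of build mm9 was at hand, so whether an enhancer lies in an exon, an intron or between genes is not given. Enhancers were 1 to 975 bp wide (median 194 bp), and a gene had a median of 2 enhancers and at most 74.

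The comparisons, their measures, the gene lists, the rule for naming genes and most of the settings to be varied were fixed before the data were examined, with a form for tables of pooled values, which applied here. Each comparison was the log2 ratio of the signal in the group named first to that in the group named second, with a pseudocount added to both. The pseudocount was the 25th percentile of all values of the assay's columns rounded to 1 significant digit: 0.65 gave 0.7 for H3K27ac, 2.44 gave 2 for H3K4me1 and 0.635 gave 0.6 for PU.1. The first lies almost midway between 0.6 and 0.7, so 0.6, used in a first look at the values, was added as an alternative. Enhancers with a log2 ratio of at least 1 in size were counted as at least 2-fold higher or lower, with no filter and no test, and the counts were repeated after subtracting the median log2 ratio of all enhancers. Comparisons were preGM with LSK, GMP with preGM, granulocytes with GMP (the histone marks only), and KO with wild type preGM. GMP with LSK defined the gained and lost enhancers, those at least 2-fold higher or lower in GMP, and KO preGM with LSK was added as a description.

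The genes named are, per comparison, those of the 6 enhancers with the highest and the 6 with the lowest log2 ratio among the 2-fold enhancers with at least the median signal in the higher group. To these come members of the fixed lists, at most 4 in the main direction of those at least 2-fold different and at most 2 in the other. A few more are named beside a count of 5 or fewer, as neighbours at the Cebpa locus or among the strongest CEBPA enhancers, and these were chosen after their values were seen. Cebpa and Spi1 were to be reported in the KO comparison whatever their values. Some genes that this rule would name are not reported here. The lists were stem and multipotent progenitor genes, myeloid transcription factors, primary granule proteins, secondary granule and mature neutrophil genes, monocyte and macrophage genes, growth factor and cytokine receptors, cell cycle genes, and markers of erythroid cells, megakaryocytes, B cells, T and NK cells, dendritic cells, and mast cells, basophils and eosinophils. A list's gene was represented by its assigned enhancer with the highest mean signal over the columns of the assay. The list median was ranked among 10000 random lists drawn from 20 bins of mean signal, and gained and lost enhancers were ranked the same way. For the CEBPA signal in wild type preGM, enhancers were put in 5 equal groups, and the difference of the top and bottom medians has a 95% interval from 1000 draws of genes with replacement.

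The steps were tested on simulated data made from the wild type preGM columns with 100 enhancers at each planted fold. A planted 4-fold difference was counted at 64% of H3K27ac, 59% of H3K4me1 and 83% of PU.1 enhancers, and a planted 8-fold difference at 77%, 83% and 83%, none in the wrong direction. Of the 43802 enhancers without a difference 0% were counted. The noise put into each simulated column, a standard deviation of 0.15 log2, was chosen and not estimated, as the real columns have no replicates. It is too small to carry an unchanged enhancer to 2-fold. The 0% therefore says nothing about false counts in the real columns. Sets of 300 enhancers with no planted difference fell at percentiles 94.3, 2.8 and 57.1 of the random sets, and lowered sets at percentile 0 in all assays. Alternatives were median-centred ratios, a pseudocount 4 times smaller (0.175, 0.5 and 0.15 for H3K27ac, H3K4me1 and PU.1) or 4 times larger (2.8, 8 and 2.4), and 10 groups in place of 5. Added after the data were seen were the pseudocount of 0.6 for H3K27ac, a filter keeping enhancers with a mean above the pseudocount, sets of at least 1.5-fold and 4-fold, and random sets matched on the preGM columns. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, with a fixed random seed.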

Results

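The data describe 44002 mouse enhancers in bone marrow cells on the path from multipotent progenitors to granulocytes. LSK cells are lineage-negative progenitors with Sca-1 and Kit on their surface, preGM and GMP are successive granulocyte-monocyte progenitors, and granulocytes are the mature cells. For each enhancer there was 1 signal value per group for H3K27ac, a histone mark of active enhancers, and for H3K4me1, a mark of enhancers whether active or poised. Both marks were given in LSK, preGM, GMP and granulocytes and in preGM from Cebpa knockout (KO) mice. PU.1, a transcription factor of myeloid cells, was given in LSK, preGM, GMP and KO preGM, and CEBPA, the factor encoded by the deleted gene, in wild type preGM. Each of these 15 groups had 2 libraries per the labels, which the table does not separate, so there are no replicates in the values below and no test of any difference between groups. The enhancers were assigned to 10096 genes, lay on 20 chromosomes and had a median width of 194 bp (build mm9). The table gives no depth, so the counting precision of each value is unknown.

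Signal values are in the authors' units. Log2 ratios were computed with a pseudocount and are given after subtracting the median log2 ratio of all enhancers in that comparison, except where stated. That median was 0.025, 0.29 and 0.14 for H3K27ac in the steps from LSK to preGM, preGM to GMP and GMP to granulocytes, and 0.046 for KO against wild type preGM. It was -0.061, 0.21, 0.32 and 0.10 in the same order for H3K4me1. For PU.1 it was 0.30 and -0.069 in the first and second steps and -0.27 in the KO. Counts of enhancers at least 2-fold higher or lower use ratios before the subtraction, and the counts after it follow where they matter. A listed gene is represented by its enhancer with the highest mean signal, and the median of a list stands beside its percentile among 10000 random lists of enhancers with like signal. Enhancers are not independent replicates, so these percentiles and the intervals below describe the columns at hand only. The 13 lists were set against random lists in 11 pairs of assay and comparison, 143 medians in all, so some extreme percentiles arise by chance. Genes such as Flt3, Kit, Csf1r, Csf3r and Irf8 stand in more than 1 list.

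The step from LSK to preGM is the entry into the granulocyte-monocyte lineage. H3K27ac was already higher in preGM at enhancers of some primary granule genes, which encode the first granule proteins made by myeloid progenitors. At Ctsg, cathepsin G, it was 3.13 in preGM against 0.684 in LSK, a log2 ratio of 1.44. At Mpo, myeloperoxidase, it was 6.44 against 2.24, a log2 ratio of 1.25. These were 2 of the 5 measured primary granule genes, whose median was 0.73 at percentile 99.8. Of 13 myeloid transcription factors, Myb, a proto-oncogene of progenitor proliferation, alone was at least 2-fold higher, with 12.5 against 4.25, and the list median was 0.48 at percentile 91.1. An enhancer of Cebpa (chromosome 7, 35908358 to 35908519) was among the 6 with the largest log2 ratios, at 3.85 in preGM against 0.900 in LSK, and so was one of Tgfbi, a secreted matrix protein, at 3.25 against 0.613. Of 15 secondary granule and mature neutrophil genes none was at least 2-fold different, and their median was -0.32 at percentile 1.16.

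Of 20 stem and multipotent progenitor genes, Erg, an ETS factor of stem cells, was at least 2-fold higher in preGM at 8.59 against 3.76, none was lower, and the median was 0.055 at percentile 33.1. Of 17 monocyte and macrophage genes 1 was at least 2-fold lower and none higher, although the list median was positive, 0.15 at percentile 83.9. No member of the cytokine receptor list (0.41 at percentile 86.2) or the cell cycle list (0.089 at percentile 18.2) was at least 2-fold different. The other enhancers with the largest log2 ratios were assigned to Zfp821, at 3.56, Arf6, a small GTPase of membrane traffic, at 2.50, Brpf3 at 1.54 and Pard6g at 1.47. Those of Zfp821 and Arf6 had unusual values in several assays, given at the end. The lowest were assigned to Cyb561 at -1.44, Eml4 at -1.43, Dmbx1 at -1.42, Spry1, an inhibitor of receptor tyrosine kinase signalling, at -1.40, Cbfa2t3, a corepressor, at -1.38 and Rnaseh2c at -1.35. Median H3K27ac log2 ratios of marker lists of other cell types were B 0.15 at percentile 68.3, T and NK -0.061 at percentile 30.1, dendritic 0.027 at percentile 50.4, erythroid 0.10 at percentile 33.4, and megakaryocyte 0.068 at percentile 49.9. The list of mast cell, basophil and eosinophil genes had 1 measured gene, Prg2, at 0.88. In all 317 enhancers were at least 2-fold higher and 160 at least 2-fold lower, 66.5% of these being higher. After the subtraction there were 247 higher and 201 lower, 55.1% being higher. With a pseudocount 4 times smaller the balance turned, to 1658 higher and 2232 lower.

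PU.1 signal was higher in preGM than in LSK at many enhancers, among them those of some primary granule and monocyte genes. It was at least 2-fold higher at 3 of 5 primary granule genes, Elane, which encodes neutrophil elastase, at 5.99 against 1.74, Mpo at 7.20 against 2.31, and Ctsg at 2.28 against 0.574 (2 of them after the subtraction), with a median of 1.00 at percentile 99.98. It was also at least 2-fold higher at 5 of 17 monocyte genes, 1 after the subtraction, with a median of 0.51 at percentile 99.9. Fn1, fibronectin, Ms4a6c, F13a1, a coagulation factor subunit, and Cx3cr1, the fractalkine receptor, had log2 ratios of 1.12, 0.99, 0.98 and 0.90. Of 11 receptor genes 2 were at least 2-fold higher, 1 after the subtraction, Il6ra, the interleukin-6 receptor, at 43.4 against 16.8 and Il1r2, a decoy receptor for interleukin-1, at 11.2 against 4.94, with a median of 0.52 at percentile 97.4. Cxcr2, a chemokine receptor of neutrophils, at 14.1 against 4.31, and Ltf, lactoferrin, at 5.30 against 2.05, were 2 of 15 secondary granule and neutrophil genes at least 2-fold higher, 1 after the subtraction, 8 of the 15 lay above the median of all enhancers, and the list median was 0.086 at percentile 77.0. Sox4, at 12.5 against 4.69, was the 1 of 13 myeloid transcription factors at least 2-fold higher, with a list median of 0.25 at percentile 47.5, and none of 20 stem and progenitor genes differed by 2-fold, with 0.12 at percentile 35.9. Aurkb, aurora kinase, and Mcm5, a subunit of the replication helicase, were 2 of 11 cell cycle genes at least 2-fold higher, none after the subtraction, at 0.80 and 0.92, with a list median of 0.044 at percentile 39.6. Medians of the lists of other cell types were B 0.18 at percentile 57.3, T and NK 0.44 at percentile 95.1, dendritic -0.0025, 0.29 before the subtraction, at percentile 14.3, erythroid 0.24 at percentile 65.6, and megakaryocyte 0.35 at percentile 53.7, and Prg2 was at 0.083. Itgax, an integrin shared by myeloid cells, was the 1 of 4 dendritic cell genes at least 2-fold higher, none after the subtraction, at 0.85. The largest log2 ratios were at enhancers of Hpcal1 (20.2 against 1.88) and Ncf4, a subunit of the phagocyte NADPH oxidase (chromosome 15, 78088759 to 78088905, 19.8 against 2.26), followed by Zcchc8, Epc2, Kif23 and Ppt1. The lowest was at Irf2bp2, at 0.128 against 1.02. In all 2888 enhancers were at least 2-fold higher and 16 at least 2-fold lower, and after the subtraction the counts were 970 higher and 264 lower.

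Few enhancers differed by 2-fold in H3K4me1 between LSK and preGM: 1, assigned to Zfp821, was at least 2-fold higher in preGM, and 3, assigned to Cyb5rl, Spag1 and Gpr132, were at least 2-fold lower. After the subtraction the counts were 2 higher and 1 lower. No listed gene differed by 2-fold at its strongest enhancer. List medians were nonetheless high for primary granule genes, 0.19 at percentile 99.9, secondary granule genes, 0.10 at percentile 97.1, and the B and dendritic cell lists, 0.12 at percentile 98.5 and 0.047, -0.015 before the subtraction, at percentile 98.4, and low for myeloid transcription factors, -0.26 at percentile 1.39.

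The step from preGM to GMP is the maturation of the committed progenitor. The primary granule genes stood out: H3K27ac at the strongest enhancer of Mpo was 43.8 in GMP against 6.44 in preGM, a log2 ratio of 2.35. Ctsg had 17.7 against 3.13, Elane 5.93 against 1.49, and Prtn3, proteinase 3, 7.13 against 2.97. These 4 of 5 primary granule genes, 3 after the subtraction, were at least 2-fold higher, and the list median was 1.30 at percentile 100. Among 13 myeloid transcription factors Zeb2, Gfi1, a repressor needed for granulocyte development, and Runx1, a master factor of blood formation, were higher, with log2 ratios of 1.54, 1.40 and 0.84, 2 of the 3 after the subtraction, although the list median of 0.18 at percentile 3.87 was low for enhancers of like signal. Flt3, a receptor of early progenitors, had H3K27ac of 2.46 in GMP against 10.8 in preGM, and Meis1, a homeobox factor of stem cells, 1.15 against 3.85. These 2 of the 20 stem and progenitor genes were at least 2-fold lower, none was higher, and the list median was -0.31 at percentile 0.04.

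Of 15 secondary granule and neutrophil genes, Csf3r, the receptor for granulocyte colony-stimulating factor, and Ngp, neutrophilic granule protein, were at least 2-fold higher (Csf3r alone after the subtraction), with a list median of 0.18 at percentile 86.3. The 11 cytokine receptor genes went both ways: Tnfrsf1a, a receptor for tumour necrosis factor, Csf3r and Ifngr1, an interferon gamma receptor subunit, were higher at 1.33, 1.01 and 0.83, while Flt3 and Il1r2 were lower at -2.15 and -1.38. The receptor median was -0.040, 0.25 before the subtraction, at percentile 0.66. Cell cycle genes were higher at Rrm2, ribonucleotide reductase, Cdk1, the mitotic kinase, Top2a, topoisomerase, and Aurkb, 4 of 11 genes, 1 after the subtraction, with a median of 0.57 at percentile 91.1. None of 17 monocyte genes differed by 2-fold, and the median was 0.10 at percentile 52.9. Medians of the lists of other cell types were B 0.54 at percentile 97.4, T and NK -0.72 at percentile 0.31, dendritic -0.33 at percentile 8.99, erythroid 0.26 at percentile 40.8, and megakaryocyte -0.33 at percentile 3.78, and after the subtraction 1 of the 4 measured B cell genes was at least 2-fold lower although the median was positive. Gata3, a T cell factor and the 1 of 5 T and NK cell genes that was at least 2-fold lower (2 after the subtraction), was at 0.254 in GMP against 1.27 in preGM, and Prg2 was at 0.40. The enhancers with the largest log2 ratios included 3 of Mpo on chromosome 11, starting at 87614218, 87611717 and 87610360, 2 of Celsr3, and 1 of Alas1, the first enzyme of haem synthesis (chromosome 9, 106149368 to 106149540, 10.7 against 0.892). Those with the lowest were assigned to Zfp821 (1.87 against 45.6), Arf6, Flt3 (2 enhancers), Tox and Cdx2. In all 4052 enhancers were at least 2-fold higher and 181 at least 2-fold lower, 95.7% being higher, and after the subtraction the counts were 1219 higher and 936 lower, 56.6% being higher.

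PU.1 differed between preGM and GMP in both directions. At S100a8, a calcium-binding protein of neutrophils, it was 6.76 in GMP against 1.80 in preGM, and at Elane 16.3 against 5.99. Primary granule genes had a median of 0.31 at percentile 97.7. Stem and progenitor genes were low for enhancers of like signal, with a median of -0.48 at percentile 0: 2 of 20 were at least 2-fold lower, Prdm16 at 1.79 against 6.30 and Hlf at 5.33 against 12.6, both transcription factors of stem cells. Itga2b, the platelet integrin, was lower at 9.18 against 21.2, and the megakaryocyte list had a median of -0.80 at percentile 0.05, the T and NK cell list -0.53 at percentile 0.41. The medians of the B, dendritic and erythroid lists were -0.016 at percentile 73.9, -0.00046 at percentile 62.5 and 0.12 at percentile 85.3, and Prg2 was at -0.41. The largest ratios were at enhancers of Arf6 (63.6 against 3.89), Zfp821, 4831426I19Rik, Limk2, Neu1 and Prom1, and the lowest at Gtf3c5 (1.08 against 6.01), Clnk, Atoh8, Capn3, Spice1 and Dcaf7. In all 338 enhancers were at least 2-fold higher and 341 at least 2-fold lower, and after the subtraction the counts were 441 higher and 236 lower, while with a pseudocount 4 times smaller they were 1142 higher and 1115 lower. For H3K4me1 376 enhancers were at least 2-fold higher and 1 at least 2-fold lower, the latter at Zfp821, and after the subtraction the counts were 90 higher and 7 lower. The highest H3K4me1 ratios were at Sun2, a nuclear envelope protein, Hal, Itgb2, the leukocyte integrin beta chain, Aprt, Pgd and Cldn15, between 1.28 and 1.38. Lcn2, the iron-scavenging neutrophil protein lipocalin 2, was the only listed gene at least 2-fold different in H3K4me1, at 4.98 against 0.976, and the receptor list had a median of 0.13 at percentile 99.7.

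From GMP to granulocytes the primary and secondary granule genes went in opposite directions. H3K27ac at Mpo was 1.29 in granulocytes against 43.8 in GMP, a log2 ratio of -4.63, and at Ctsg 0.821 against 17.7. Of 5 primary granule genes 4 were at least 2-fold lower, the others being Prtn3 at -1.76 and Elane at -1.61, with a list median of -1.76 at percentile 0.12. Of 15 secondary granule and mature neutrophil genes 10 were at least 2-fold higher and none lower, with a median of 1.09 at percentile 99.99. Itgb2l, a neutrophil integrin chain, had 6.62 in granulocytes against 0.657 in GMP, Mmp9, a gelatinase, 6.31 against 0.951, Cxcr2 7.54 against 1.25, and Lcn2 5.95 against 0.909. Over all enhancers assigned to these genes, 91 of 134 were at least 2-fold higher and none lower. Of 20 stem and progenitor genes 8 were at least 2-fold lower, 10 after the subtraction, and none higher, with a median of -0.95 at percentile 0.03. The largest differences were at Kit, the stem cell factor receptor, at -1.87, Tal1 at -1.65, Hoxa9 at -1.57 and Flt3 at -1.54. Of 13 myeloid transcription factors 8 were at least 2-fold lower, among them Myb at 2.71 against 18.6, Sox4 at -2.45, Myc, a driver of growth and division, at -2.30 and Irf8, a factor of monocyte fate, at -1.53. Cebpb alone was higher, at 12.8 against 5.02, and the list median was -1.17 at percentile 0.16.

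Among monocyte genes the count and the median had different signs: 3 of 17 were at least 2-fold lower, Ly86, a partner of a Toll-like receptor, at -1.71, Irf8, and Klf4 at -1.34, none was higher, and the median was 0.22 at percentile 94.5. Among 11 receptor genes Il1r2 and Csf2ra, the alpha chain of the receptor for granulocyte-macrophage colony-stimulating factor, were higher at 3.49 and 1.04, Kit and Flt3 were lower, and the median was 0.27 at percentile 93.8. None of 11 cell cycle genes differed by 2-fold, 2 were lower after the subtraction, and the median was -0.66 at percentile 7.25. Medians of the lists of other cell types were B -0.70 at percentile 5.86, T and NK 0.028 at percentile 67.8, dendritic 0.41 at percentile 88.9, erythroid -1.04 at percentile 3.51, and megakaryocyte -0.15 at percentile 53.3. Zfpm1, a partner of GATA factors, and Car2, carbonic anhydrase 2, of the erythroid list were lower at -1.89 and -1.34, Itga2b of the megakaryocyte list at -1.25 and Prg2 at -1.27. In the dendritic cell list Itgax was higher at 1.53 and Tcf4 lower at -1.86. The enhancers with the largest ratios were assigned to Il1r2 (chromosome 1, 40142081 to 40142211, 14.5 against 0.524), Ldha, lactate dehydrogenase (10.1 against 0.201), 1700067P10Rik, Gngt2, Slc16a3, a lactate exporter, and Ntng2. The 6 lowest were 5 enhancers of Mpo, down to -4.63 at chromosome 11, 87608943 to 87609089, and the enhancer of Ctsg at chromosome 14, 56720767 to 56721138. In all 6188 enhancers were at least 2-fold higher and 2661 at least 2-fold lower, 69.9% being higher, and after the subtraction the counts were 4771 higher and 3627 lower, 56.8% being higher.

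**Figure D1:**
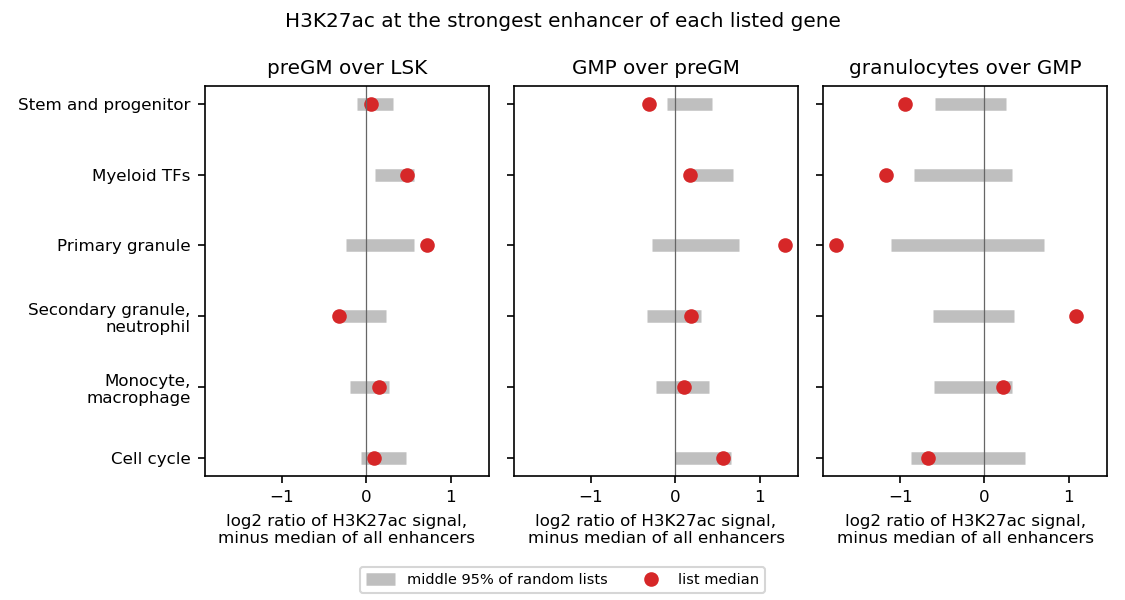
Median log2 ratio of H3K27ac signal (red points, horizontal axis, after subtraction of the median of all enhancers) at the strongest enhancer of each gene in 6 lists, for each of the 3 steps from LSK to granulocytes, with grey bars for the middle 95% of 10000 random lists of like signal. Primary granule genes lie at 0.73, 1.30 and -1.76 in the 3 steps, and secondary granule and neutrophil genes at -0.32, 0.18 and 1.09.

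H3K4me1 was also higher in granulocytes than in GMP at secondary granule genes: 6 of 15 were at least 2-fold higher, 5 after the subtraction, and none lower, with a median of 0.50 at percentile 99.6. S100a9, the partner of S100a8, had 8.16 against 0.892, Ltf 7.84 against 1.04, Itgb2l 9.26 against 1.97, and Cd177, a neutrophil surface protein, 7.83 against 1.63. Cell cycle genes had higher H3K4me1 at their enhancers strongest in H3K4me1. At their enhancers strongest in H3K27ac, none differed by 2-fold in H3K27ac before the subtraction. Of 11 genes 6 were at least 2-fold higher, 1 after the subtraction, with a median of 0.77 at percentile 100, and Mcm5 had 10.5 against 2.07. Myc and Cebpa, whose H3K27ac was lower in granulocytes at the enhancer strongest in H3K27ac, had H3K4me1 of 14.8 against 4.11 and 16.2 against 6.08 at the enhancer strongest in H3K4me1. They were 2 of the 3 myeloid transcription factors of 13 that were at least 2-fold higher, the other being Gfi1, whereas after the subtraction 1 was higher and 1 lower and the list median was 0.091 at percentile 52.1. Over the 16 enhancers assigned to Cebpa, H3K27ac went both ways from GMP to granulocytes. The enhancer starting at 35904704, its strongest, had 6.63 in granulocytes against 14.1, and that at 35912297 had 6.23 against 1.95. Stem and progenitor genes were low for enhancers of like signal, with a median of -0.42 at percentile 0.28. Mecom, a transcription factor of stem cells, had 1.09 against 5.97 and Hoxa9 1.13 against 5.61. Kit was higher at 14.9 against 4.79, less than 2-fold after the subtraction.

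Cd68, a lysosomal protein of macrophages, was the 1 of 17 monocyte genes at least 2-fold higher in H3K4me1, whereas after the subtraction none was higher and 4 were lower. The highest enhancers were those of Plin4, a lipid droplet protein (18.5 against 1.24), Mxd1, an antagonist of MYC (11.1 against 0.607), 1500002O20Rik, Coq4 and Cd177 (2 enhancers). The lowest were assigned to Haao, an enzyme of tryptophan breakdown, Gse1 and St6galnac5, between -2.02 and -2.00. The overall H3K4me1 balance turned with the subtraction: 4265 enhancers were at least 2-fold higher and 1235 at least 2-fold lower before it, against 1511 higher and 4508 lower after it. PU.1 was not analysed here in granulocytes.

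Over both early steps together, from LSK to GMP, H3K27ac was at least 2-fold higher at 6666 and lower at 224 enhancers (3447 higher and 1163 lower after the subtraction). The corresponding counts were 980 and 106 for H3K4me1 (470 higher and 209 lower) and 3224 and 123 for PU.1 (2024 higher and 323 lower). The highest H3K27ac ratios were at Ctsg, 3.80, and Mpo, 3.70, and the lowest at Hoxa9, -2.26, and Mecom, -2.01. These enhancers, called gained and lost below, serve to ask what happens to them in KO preGM.

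Cebpa encodes a transcription factor required for the formation of GMP, and the comparison of KO with wild type preGM asks how enhancers differ without it. The enhancers of the targeted gene itself served as a check of the labels. At 1 of the 16 enhancers assigned to Cebpa (chromosome 7, 35906741 to 35906988) KO preGM had H3K27ac of 0.0320 against 0.812 in wild type, H3K4me1 of 0.00686 against 3.14, and PU.1 listed at 0 against 0.406. Each of these KO values was the lowest of all 44002 enhancers in its column. The position of the deleted segment was not given in the sources used here, so which of the 16 enhancers lie inside it is unknown. H3K4me1 was also at least 2-fold lower at 2 neighbouring enhancers, starting at 35904704 (0.857 against 3.99) and 35905728 (0.300 against 4.41), where H3K27ac was 14.9 against 7.48 and 8.0 against 4.09. On the other side, at 35908358 and 35909054, H3K27ac was lower in the KO, at 1.40 against 3.85 and 1.43 against 3.98, and at 35910817 and 35925086 it was higher, at 1.35 against 0.230 and 1.79 against 0.452. The strongest PU.1 enhancer of Cebpa, at 35936013 to 35936072, had PU.1 of 7.43 in the KO against 19.2. No enhancer was assigned to Spi1, the gene of PU.1.

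**Figure D2:**
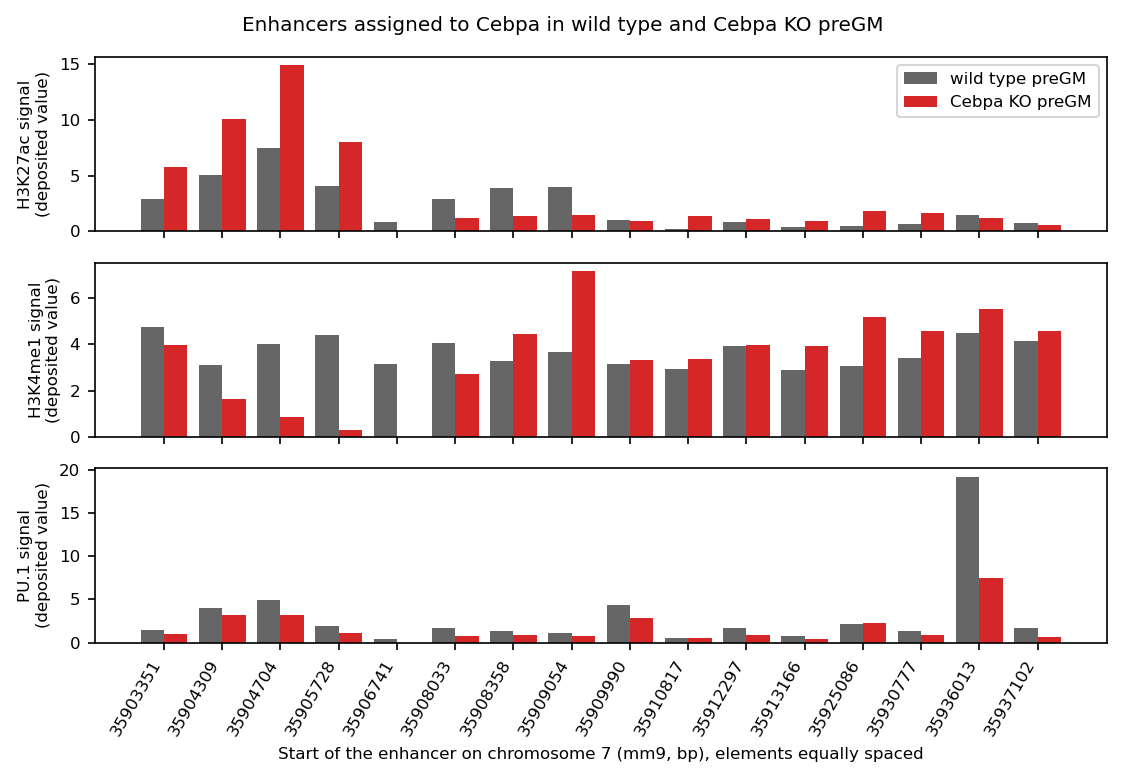
Signal of H3K27ac, H3K4me1 and PU.1 (vertical axes, deposited values) at the 16 enhancers assigned to Cebpa, in order along chromosome 7, with grey bars for wild type and red bars for KO preGM. At the enhancer starting at 35906741 the KO bars are 0.0320, 0.00686 and 0, and at 35936013 PU.1 is 7.43 in the KO against 19.2.

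Outside the Cebpa locus few listed genes differed by 2-fold in H3K27ac. Il6ra had H3K27ac of 1.00 in the KO against 4.87 in wild type (chromosome 3, 89716384 to 89716786), and Flt3 4.27 against 10.8. These were 2 of 11 receptor genes, none was higher, and the list median was -0.19 at percentile 1.5. Ctsg had 0.882 against 3.13, the 1 of 5 primary granule genes that was at least 2-fold lower, and the list median was -0.34 at percentile 2.43. Of 20 stem and progenitor genes Flt3 and Gata2, a transcription factor of stem cells at 1.69 against 4.33, were lower. Mycn, a relative of Myc, was higher at 4.41 against 1.29, and the list median was -0.30 at percentile 0.07. None of 13 myeloid transcription factors or 17 monocyte genes differed by 2-fold, with medians of -0.13 at percentile 3.52 and -0.16 at percentile 5.63. S100a9 was the 1 of 15 secondary granule genes that was at least 2-fold higher, 0.977 against 0.123, just under 2-fold after the subtraction, with a list median of 0.15 at percentile 87.6.

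Car2 of the erythroid list had H3K27ac of 4.93 in the KO against 1.59. Medians of the lists of other cell types were B 0.20 at percentile 78.3, T and NK 0.28 at percentile 89.9, dendritic 0.037 at percentile 57.4, erythroid 0.061 at percentile 47.3, and megakaryocyte 0.066 at percentile 55.3, Prg2 was at -0.64, and cell cycle genes had -0.0083, 0.037 before the subtraction, at percentile 33.6. The highest enhancers in the KO were those of Haao (chromosome 17, 84306206 to 84306463, 10.2 against 1.69), Fibcd1 (6.44 against 1.07 and 3.68 against 0.726), Arpp21, Fnbp1l and Mta3. The lowest were those of Cnnm4 (0.298 against 2.83), Il6ra, Camk2n2, Snx18, Id2, an inhibitor of helix-loop-helix factors (0.181 against 1.76), and Tgfbi (0.809 against 3.25). In all 194 enhancers were at least 2-fold higher and 207 at least 2-fold lower, 48.4% being higher, and after the subtraction the counts were 142 higher and 289 lower, 32.9% being higher. With a pseudocount of 0.6 in place of 0.7, a setting chosen after the data were seen, 302 were higher and 321 lower, and with a pseudocount 4 times smaller, the balance turned to 1945 higher and 1664 lower.

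For H3K4me1, 4 enhancers were at least 2-fold lower in the KO and none higher: the 3 of Cebpa given above and 1 of Zfp821, at 5.72 against 16.0. That wild type value of Zfp821 was the highest of all enhancers in its column. No listed gene differed by 2-fold at its strongest enhancer. Monocyte and secondary granule genes were low for enhancers of like signal, with medians of -0.088, 0.016 before the subtraction, at percentile 0.06 and -0.12 at percentile 1.40, and stem and progenitor genes were at 0.11 at percentile 94.2. The gained H3K4me1 enhancers, 980 in number, had a median log2 ratio of -0.15 before the subtraction in the KO, against 0.11 for enhancers neither gained nor lost and 0.024 for random sets of like signal over all H3K4me1 columns or -0.034 for sets matched on the 2 preGM columns, a matching added after the data were seen, and lay below all 10000 sets of both kinds. Of the gained enhancers 91.0% lay below the median of all enhancers. The 106 lost enhancers had 0.14 before the subtraction. This median was at percentile 99.6 of random sets matched on all H3K4me1 columns but 24.5 of sets matched on the 2 preGM columns. Across all enhancers, which are not independent replicates, the KO log2 ratio and the GMP over LSK log2 ratio of H3K4me1 had a Pearson correlation of -0.36 and a Spearman correlation of -0.33. For H3K27ac these were 0.020 and 0.026. The 6666 gained H3K27ac enhancers had a median of 0.095 before the subtraction, above the 0.035 of the rest. They lay below all 10000 random sets of like signal, whose median was 0.14 before the subtraction. The 224 lost ones had 0.092 before the subtraction, at percentile 98.2. The difference between gained H3K27ac enhancers and the rest turned to -0.087 for the 194 gained by at least 4-fold, a set chosen after the data were seen.

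PU.1 signal was lower in KO preGM at enhancers of some primary granule genes, monocyte genes and myeloid transcription factors. Elane had a PU.1 value of 0.977 in the KO against 5.99 in wild type, and Mpo 2.50 against 7.20, 2 of 5 primary granule genes, with a list median of -0.60 at percentile 2.18. Of 17 monocyte genes 6 were at least 2-fold lower, 5 after the subtraction, and none higher, with a median of -0.63 at percentile 0.51. Cd68 had 3.04 against 11.3, F13a1 3.27 against 9.88, Ms4a6c 2.99 against 8.65, and Ctss, a lysosomal protease, 8.40 against 21.9. Of 13 myeloid transcription factors 4 were at least 2-fold lower, 3 after the subtraction, with a median of -0.64 at percentile 4.07. They were Myb at 2.17 against 8.53, Cebpa, Sox4 at 4.76 against 12.5 and Id1, an inhibitor of helix-loop-helix factors, at 2.96 against 7.34. Of 11 receptor genes Il6ra (16.1 against 43.4), Csf1r, the receptor for macrophage colony-stimulating factor (16.7 against 39.1), and Il1r2 were lower, 1 of them after the subtraction, yet the median of -0.39 at percentile 73.5 was not low for enhancers of like signal. Ltf (1.03 against 5.30) and Cxcr2 (4.63 against 14.1) were 2 of 15 secondary granule genes, whose median was -0.11 at percentile 38.9.

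Lmo2 was the 1 of 20 stem and progenitor genes with PU.1 at least 2-fold lower, none after the subtraction, with a median of -0.23 at percentile 68.8. Mcm5 and Rrm2 were 2 of 11 cell cycle genes, none after the subtraction, with a median of -0.42 at percentile 6.11. Medians of the lists of other cell types were B -0.19 at percentile 78.9, T and NK -0.18 at percentile 51.2, dendritic 0.048, -0.22 before the subtraction, at percentile 96.6, erythroid 0.035, -0.23 before the subtraction, at percentile 95.4, and megakaryocyte -0.55 at percentile 41.8, and Prg2 was at -0.48. The lowest enhancers were those of Chmp6, a membrane remodelling protein (chromosome 11, 119668758 to 119668997, 0.673 against 8.89), Ctdp1, Capzb, an actin capping protein (1.62 against 12.2), Ctsz, a lysosomal protease (0.639 against 6.37), Zcchc8 and 2310004I24Rik. The highest were those of Zfp821 (39.6 against 5.74), Arf6 (19.5 against 3.89), Pion (2 enhancers), Stim1 and Mpp4. In all 42 enhancers were at least 2-fold higher and 2707 at least 2-fold lower, at 40 and 1794 genes. After the subtraction the counts were 319 higher and 875 lower, 26.7% being higher in place of 1.53%.

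The PU.1 difference was largest at enhancers that the authors class as bound by both PU.1 and CEBPA. Median log2 ratios before the subtraction were -0.78 at the 4054 enhancers of both factors, -0.64 at the 8387 with PU.1 only, -0.25 at the 5395 with CEBPA only and -0.095 at the 26166 with neither. The criterion of these classes was not given, and no enhancer without the PU.1 label had a GMP PU.1 value of 3 or more, so they do not stand apart from the PU.1 values. By CEBPA signal in wild type preGM, PU.1 log2 ratios before the subtraction had medians of -0.19, -0.23, -0.24, -0.27 and -0.41 over 5 equal groups of enhancers from the least CEBPA to the most. The top group differed from the bottom by -0.23, with a 95% interval from -0.25 to -0.21 when genes were resampled. Among enhancers with a mean PU.1 signal above the pseudocount it was -0.11, without an interval, a filter added after the data were seen. The groups were not matched on PU.1 signal, and the KO log2 ratio also went with the PU.1 class. How much of the difference belongs to CEBPA signal itself cannot be told from these groups. PU.1 was at least 2-fold lower at 11.8% of the top group and 4.18% of the bottom. For H3K27ac the difference between top and bottom was -0.020 (from -0.034 to -0.0050), and for H3K4me1 -0.0018 (from -0.0086 to 0.0046). The 3224 enhancers that gained PU.1 from LSK to GMP had a median KO log2 ratio of -0.78 before the subtraction, against -0.24 for the rest and -0.49 for random sets of like signal, below all 10000 of these, and 33.0% of them were at least 2-fold lower. The 123 that lost PU.1 had -0.29 before the subtraction, above all random sets, whose median was -0.49. Across all enhancers the KO log2 ratio of PU.1 and its GMP over LSK log2 ratio had a Pearson correlation of -0.38 and a Spearman correlation of -0.33.

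**Figure D3:**
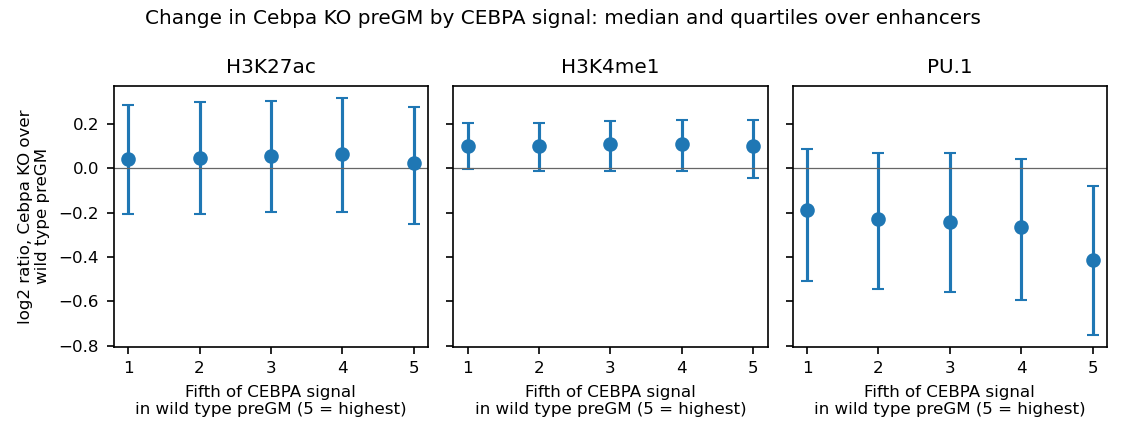
Median (points) and quartiles (bars) of the log2 ratio of KO over wild type preGM signal, before subtraction of the overall median, across enhancers in 5 equal groups by CEBPA signal in wild type preGM (horizontal axis, 5 = highest), for H3K27ac, H3K4me1 and PU.1. PU.1 medians go from -0.19 in the first to -0.41 in the last group, while H3K27ac medians stay between 0.023 and 0.065.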

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

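The filter on low signal, the sets of at least 1.5-fold and 4-fold, the pseudocount of 0.6 and the matching on the preGM columns were chosen after the data were seen, and the other settings were planned. No paired analysis was possible because the columns carry no replicates, and for the same reason leaving out replicates, a replicate block and a choice of samples in a fit were not possible. The scaling was varied only by subtracting the median and, in a test given further below, by giving both H3K4me1 preGM columns the same distribution. The planned setting of no filter and the planned set definition of at least 2-fold are those of the main values. With the median subtracted, the count of enhancers at least 2-fold different became 2155 for H3K27ac and 97 for H3K4me1 in GMP against preGM, and 1234 for PU.1 in preGM against LSK and 1194 in KO against wild type while 10 other results moved by less than 1.5 times, for counts, or stayed within their interval. With the filter 13 results stayed so, and with the pseudocount of 0.6 it was 6. With a pseudocount 4 times smaller, the counts for preGM against LSK, GMP against preGM, granulocytes against GMP and KO against wild type were 3890, 10100, 14492 and 3609 for H3K27ac and 106, 2584, 12759 and 83 for H3K4me1, and without granulocytes 6383, 2257 and 6111 for PU.1. With a pseudocount 4 times larger they were 4, 524, 2300 and 3 for H3K27ac, 0, 1, 69 and 0 for H3K4me1, and 704, 104 and 676 for PU.1. The counts thus depend on the pseudocount by construction, since it sets how far a low signal can differ. The pseudocount of 0.6 gave 623 for H3K27ac in the KO. Which direction held more enhancers turned with the median subtracted for H3K4me1 in preGM against LSK (2 higher, 1 lower) and granulocytes against GMP (1511 higher, 4508 lower) and for PU.1 in GMP against preGM (441 higher, 236 lower). It turned with the smaller pseudocount for H3K27ac in preGM against LSK (1658 higher, 2232 lower) and in the KO (1945 higher, 1664 lower) and for H3K4me1 in preGM against LSK (78 higher, 28 lower), and with the larger one for H3K27ac in the KO (2 higher, 1 lower) and H3K4me1 in GMP against preGM (0 higher, 1 lower). For PU.1 in GMP against preGM it turned with both (1142 higher, 1115 lower and 61 higher, 43 lower). The median KO ratio of gained enhancers minus that of the rest, -0.25 for H3K4me1 and -0.54 for PU.1, kept its sign in all settings that gave a value. For H3K4me1 it was -0.28 with the median subtracted, -0.33 with the smaller pseudocount and -0.19 for sets of at least 1.5-fold. For PU.1 it was -0.61, -0.38 and -0.39 in the same settings, -0.63 with the larger pseudocount and -0.89 for 4-fold sets. For H3K27ac it was 0.059, with 0.034 with the smaller and 0.093 with the larger pseudocount, 0.038 for 1.5-fold sets, and -0.087 for 4-fold sets of 194 enhancers. For lost enhancers the PU.1 difference of -0.052 turned to 0.029 with the median subtracted, 0.19 with the smaller pseudocount and 0.017 for 1.5-fold sets. Lost sets under 20 enhancers gave -0.15 (9 enhancers, larger pseudocount) and -0.18 (1 enhancer, 4-fold) for PU.1, -0.53 (2 enhancers, larger pseudocount) against 0.057 for H3K27ac, and 0.27 (1 enhancer, larger pseudocount) against 0.028 for H3K4me1. The 4-fold sets of lost H3K27ac enhancers and of gained and lost H3K4me1 enhancers, and the gained H3K4me1 set with the larger pseudocount, were empty and gave no value. Against random sets matched on the preGM columns, the difference was -0.11 in place of -0.17 for gained H3K4me1 enhancers, -0.32 in place of -0.29 for gained PU.1 enhancers, and -0.011 in place of 0.050 for lost H3K4me1 enhancers. For the top and bottom groups by CEBPA signal, the PU.1 difference of -0.23 was -0.35 with 10 groups, -0.15 with the larger pseudocount and -0.11 with the filter, and the H3K4me1 difference of -0.0018 was -0.011 with the smaller and 0.0020 with the larger pseudocount. Where a sign turned, the cause was not tested. Depth is unknown, so its limit on these values could not be given.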

Other observations

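Of the tests below, those of the wider range of the KO column and of the gained enhancers with low CEBPA were written down before their results were seen, the latter when all other results were known, and the other 4 were chosen only after the result was seen. The 20 enhancers with the highest CEBPA signal in wild type preGM, picked by that signal after the data were seen, belonged to 17 genes. They included Cotl1, an actin-binding protein, at 22.6, Itgb7, a leukocyte integrin chain, at 19.5, Fut7, an enzyme that makes selectin ligands, at 16.7, Runx1 at 12.9 and Id1 at 12.5. In KO preGM the PU.1 log2 ratio, before the overall median was subtracted, was below 0 at 19 of the 20 and at least 2-fold lower at 6, among them Zbtb10 at -2.10 and Ndrg1 at -1.42. That overall median was -0.27, and the upper quartile in the top group by CEBPA signal was -0.080, so values below 0 were common. After the subtraction the PU.1 median of the 20 was -0.62. None of the 20 was at least 2-fold lower in H3K27ac or H3K4me1. Cotl1 was at least 2-fold higher in H3K27ac, at 1.15 before the subtraction. Before the subtraction the log2 ratio was below 0 at 13 for H3K27ac and at 4 for H3K4me1. The medians after the subtraction were -0.081 and 0.088.

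PU.1 in KO preGM resembled LSK more than wild type preGM in level. At enhancers of both factor classes the median PU.1 signal was 3.34 in LSK, 6.11 in wild type preGM, 3.39 in KO preGM and 6.26 in GMP, and at enhancers with PU.1 only it was 3.14, 5.01, 3.09 and 4.34. These classes do not stand apart from the PU.1 values. Over all enhancers the PU.1 columns summed lower in LSK (93176.7) and KO preGM (89027.5) than in wild type preGM (140958) and GMP (125043). Whether the resemblance comes from PU.1 binding or from the enrichment or scaling of these columns was not tested. Between KO preGM and LSK, PU.1 was at least 2-fold higher at 419 and lower at 128 enhancers, against 2888 and 16 between wild type preGM and LSK, and after the subtraction 367 higher and 156 lower against 970 higher and 264 lower. H3K27ac did not follow: 735 enhancers were at least 2-fold higher and 112 lower in KO preGM than in LSK, against 317 and 160 for wild type preGM, and after the subtraction 554 higher and 178 lower against 247 higher and 201 lower.

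PU.1 signal was lower in KO preGM than in wild type at 2707 enhancers by at least 2-fold, and 3 explanations were weighed. A single scale factor between both columns would by itself give all enhancers the same ratio. Without a pseudocount the enhancers of the PU.1 classes lay -0.619 log2 below those of neither class (interval -0.633 to -0.604). These classes do not stand apart from the wild type PU.1 values, so picking enhancers by them could itself lower the KO ratio. The test therefore cannot exclude a scale factor. At equal PU.1 signal, enhancers of both factors lay -0.130 below those with PU.1 only (interval -0.148 to -0.112). A weaker KO pull-down that acts alike on bound enhancers of equal signal would by itself give no such difference. Neither would a single scale factor. The test rests on the same classes, whose criterion is unknown, so it cannot exclude either of them. A biological explanation, that PU.1 binding that rises from LSK to GMP stays lower without Cebpa, is not decided: at equal signal the third of PU.1 enhancers with the largest GMP over LSK ratio lay -0.282 below the third with the smallest (interval -0.306 to -0.259), which restates the relation it was drawn from. All 3 explanations stay open. So do a weaker pull-down that acts differently on different bound enhancers, and an effect of the authors' unstated scaling. A less mature KO population within the sort gate was not tested for PU.1 and stays open too. A property shared by the LSK and KO preGM columns was not tested for PU.1 either and stays open. Their PU.1 values had standard deviations of 4.01 and 3.22, against 5.94 in wild type preGM and 4.86 in GMP. The GMP over LSK ratio of PU.1 rests on the LSK column.

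The lower H3K4me1 in KO preGM at enhancers that gain it from LSK to GMP was weighed against a wider range of values in the KO column. With both columns given the same distribution, the gained set still lay -0.107 below random sets of equal preGM signal, whose middle 95% spanned -0.0108 to 0.00997. A difference between these 2 distributions alone thus does not account for it. The test keeps the ranks of the enhancers, and the gained set came from GMP and LSK values as deposited. LSK and KO preGM both had wider H3K4me1 values (standard deviations 1.97 and 1.86) than wild type preGM (1.44) and GMP (1.64). A property shared by the LSK and KO columns was therefore not excluded. Loss of CEBPA bound at these enhancers was weighed as the whole cause. The 294 gained enhancers with CEBPA signal at or below the median of all enhancers still lay -0.0907 below random sets (middle 95% -0.0211 to 0.0183), against -0.118 for the other 686. The lower H3K4me1 was thus not confined to enhancers with more CEBPA signal. That median was 0.534 in a column with a 95th percentile of 1.52 and unknown depth. A value below it does not show that CEBPA was absent, so the split does not decide. The KO cells may have been a less mature population within the sort gate, which would leave the enhancers lost from LSK to GMP high. Those lay at percentile 99.6 of random sets with one matching and 24.5 with the other, so this cannot be told apart from a direct or indirect effect of losing Cebpa: the answer hangs on the matching.

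The enhancers of Zfp821 and Arf6 named in several comparisons had unusual series of values. Zfp821 (chromosome 8, 112230510 to 112231226) had H3K27ac of 3.15 in LSK, 45.6 in preGM, 1.87 in GMP, 1.10 in granulocytes and 73.3 in KO preGM, and PU.1 of 8.65, 5.74, 76.5 in LSK, preGM and GMP and 39.6 in KO preGM. Arf6 (chromosome 12, 70462536 to 70462612) had H3K27ac of 3.28, 22.2, 4.72, 10.2 and 30.0 in the same order. The Zfp821 enhancer had the highest H3K27ac of all enhancers in wild type preGM and in KO preGM, and the highest H3K4me1 in wild type preGM (16.0). CEBPA signal was 7.72 at Zfp821 and 4.96 at Arf6, against a 95th percentile of 1.52. Whether these values come from the enhancers or from the measurement was not tested.

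The authors' stage flags marked 6712 enhancers (15.3%) for LSK, 21893 for preGM, 22646 for GMP and 18698 for granulocytes. For 12032 enhancers (27.3%) the stage class named a stage whose flag was 0. Each pattern of flags always went with the same class. In these 12032 the class named every stage from the first flagged one through GMP.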
